A study of Oryza brachyantha and Oryza sativa Japonica Group and Oryza glaberrima with 38 samples.

How the data were processed

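Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on above-ground tissue of 6 grass species, per the labels' protocols. Tissue was fixed in 3% formaldehyde, chromatin was sonicated to 300 to 500 bp, and libraries were read as 90 bp pairs, with 4 g of tissue for 2-week seedlings and 8 g for 60-day tillering plants. Of 38 samples, 21 have a peak list, 16 are controls (13 input, 3 histone H3) and 1 is an antibody library, H3K36me3, which was not analysed here.

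Peaks were called per library by the authors with MACS2, after alignment with Bowtie and with bedtools also named, per the submitters' processing notes, where no versions are stated. The peak names in the deposited lists of O. sativa seedling H3K9me2 and H3K27me hold a Bowtie setting that places a multi-mapped read at 1 random site. The name in the O. sativa seedling H3K56Ac list holds the setting that keeps uniquely mapped reads, per the file contents. For the other lists the handling of multi-mapped reads is not given in the sources used here, and the peak calling threshold is not given for any. The control named in the titles was input for 18 lists and H3 for 3 (O. sativa seedling H3K9me2 replicate 2, and O. brachyantha tillering H3K4me2 and batch 1 H3K4me3). The titles name a single input for H3K9me2, H3K4me3 and H3K27me of O. brachyantha seedlings. Likewise H3K9me2 and H3K4me3 of O. sativa at tillering share an input, as do H3K9me2, H3K4me3 and H3K56Ac of O. brachyantha tillering batch 2. Marks within these sets were therefore not called against independent controls. The assembly is named in the deposited lists as tigr6 for O. sativa and RS2 for O. brachyantha, and by species name only for the others.

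Each deposited list except that of O. sativa H3K27me gives for every peak a pileup signal and 3 joined values from the authors' caller. These are the −log10 p, the fold enrichment over the control and the −log10 q. The O. sativa H3K27me list gives the authors' −log10 p, fold ratio and −log10 q in separate columns without a pileup signal. These per-peak values are the authors' own and were used here to describe or filter peaks. Most filters worked within a list, and alternatives with a common −log10 q limit compared lists as well. H3K9me2 and H3K27me lists hold broad peaks and the other marks narrow peaks, as the peak widths and the summit column show. The O. sativa H3K56Ac list has 63555 lines over 37429 intervals, because summits within 1 interval are listed separately, and intervals were merged before use. The lowest −log10 q differed between lists. It was 0.237 to 0.504 in the tillering H3K9me2 lists of O. sativa, O. glaberrima, O. punctata, L. perrieri and S. bicolor and above 1 in the other lists. Peaks with a −log10 q of at least 1 in every list were therefore used as an alternative, chosen after this was seen.

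The number of reads per library is unknown, since the lists carry no totals. The median pileup at a peak was 5.66 to 18.6 in the H3K9me2 lists and 30 to 124 in the lists of narrow peaks. Chromosome lengths were taken as the last peak end over all lists of an assembly, which gave 372 Mb for O. sativa, 285 Mb for O. glaberrima, 393 Mb for O. punctata, 259 Mb for O. brachyantha, 267 Mb for L. perrieri and 651 Mb for S. bicolor. Only numbered chromosomes were used in the main results (12 per species, 10 in S. bicolor).

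Samples were grouped by species, stage and mark from the titles, which gave 18 groups, 3 of 2 libraries and 15 of 1. The O. brachyantha tillering numbers are batches in the titles, so H3K9me2 and H3K4me3 libraries of the same batch were treated as paired in an alternative. H3K4me2, H3K9Ac and H3K27me2 came from batch 1 and H3K56Ac from batch 2, so some pairs of marks span batches. Nothing in the labels says whether libraries of a group came from separate plants. P-values over chromosomes, windows, peaks or genes measure the spread within the libraries compared and not the spread between plants.

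Tests, gene lists, the rule for named items and most alternatives were fixed before the data were examined. Covered share is the percent of chromosome length inside peaks. Overlap of lists was measured in bp, as shared bp over bp in either list (Jaccard) and as shared bp over the mean of 1000 circular shifts of 1 list along each chromosome. Its permutation p is one-sided between replicates and two-sided between marks, and the smallest p it can give is 0.001 or 0.002. For groups with several library pairs the largest p was taken. The H3K9me2 block of a chromosome is the middle segment of a least-squares fit of arm, block and arm to the covered share in 100 kb windows, where both arms share 1 mean. The block over arms change of a mark is the log2 of its covered share in the block over that in the arms, tested over chromosomes with an exact two-sided sign-flip test of all 4096 flips, whose smallest p is 0.000488. Correlations over chromosomes used 100000 resamples, two-sided. Benjamini-Hochberg adjustment was applied within each family at a threshold of 0.05. The families were pairs of marks within a species and stage, marks in block and arms, 10 species pairs, 54 gene class comparisons, 15 comparisons of marks on genes, and 7 contrasts between groups, which were added after the data were seen.

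Genes came from the RefSeq table of the O. brachyantha assembly ObraRS2, with 26302 genes on the 12 chromosomes. The build was checked by placing H3K4me3 peaks on gene ends. Per chromosome and library, 71.6% to 88.7% of protein-coding genes had a peak at an end as placed, and 29.7% to 44.0% with peaks moved by 20 kb. The table gives neither strand nor product names, which led to 2 departures from the plan. A gene counted as marked by H3K4me3, H3K4me2, H3K9Ac or H3K56Ac when a peak overlapped the 500 bp on either side of either gene end, in place of the gene start. The product-based gene lists could not be matched, so they gave no result, and 6 RefSeq gene classes (pseudogene, lncRNA, rRNA, tRNA, snoRNA, snRNA) were compared with the remaining genes, a choice made after the table was seen. A gene counted as marked by H3K9me2, H3K27me or H3K27me2 when at least 50% of its body lay in peaks. Class differences were tested with 1000 circular shifts of the peaks, on the mean of a group's libraries. Shifted peaks do not give a mean difference of 0, because classes differ in length and position, so the shifted mean is the reference for direction. No other species has a gene table here.

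Named regions are the 3 longest H3K9me2 domains per species in the tillering library with the most covered bp (peaks joined over gaps of up to 1 kb) and the chromosomes with the highest and lowest covered share. The library used for the domains was chosen after the data were seen. Named genes are the 10 longest protein-coding genes of O. brachyantha covered at 90% or more by H3K9me2 in each of 3 libraries, and such genes that also carry H3K4me3 in every library.

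Alternatives were the 50% of peaks with the highest −log10 q, joined peaks, other chromosome lengths, unplaced contigs, 50% reciprocal overlap, counts of peaks in place of bp, shifts within block and arms, windows of 50 and 500 kb, each arm with its own mean, windows within 500 kb of a boundary left out, the 2 most distant chromosomes left out, 10% of the gene body, any overlap with the gene body, Fisher's exact test (largest p over libraries), pairing by batch, and each library of a pair left out in turn. Each arm with its own mean, a common −log10 q of at least 1, 2 or 3 in every list (the last 2 for covered share, blocks, arms and contrasts between species), the edges of the H3K4me3 trough, marks on genes and gene sets by stage were added after the data were seen.

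The procedures were tested on simulated data with known answers. Of 100 simulations per case at a threshold of 0.05, independent lists of 3000 peaks were called in 1% and lists with planted overlap in 100%. Block edges were recovered to within 1 window in 100%, for planted blocks with sharp edges, independent noise and a step larger than that noise. Blocks that are short, weak or graded at the edge, as in some of the data, were not simulated. Sign-flip tests over 12 chromosomes called 8% with no difference and 100% with a planted one. Gene class comparisons with random lists, over 26302 genes, were called in 3.33% of 60, and those with planted pseudogene marking in 100% of 10. These rates do not show how the comparison behaves for marks counted over the gene body, such as H3K9me2 with its long domains. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.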

Results

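Peak lists of 7 histone H3 marks were compared in 6 grasses. They were Asian cultivated rice (Oryza sativa), African cultivated rice (O. glaberrima), the wild rices O. punctata and O. brachyantha, Leersia perrieri from the sister genus of Oryza, and Sorghum bicolor. H3K9me2, a mark of silent heterochromatin in plants, had 10 lists over all 6 species, from 60-day tillering plants and, in O. sativa and O. brachyantha, also from 2-week seedlings. The other marks were profiled in O. sativa, with 6 lists in all, and O. brachyantha, with 11. H3K4me3, H3K4me2, H3K9Ac and H3K56Ac are found on active genes, and H3K27me2 and H3K27me (the number of methyl groups is not given in the label) are methylated forms of lysine 27. The design text states the purpose as a comparison of heterochromatin between closely related genomes. Groups held 1 library except O. sativa seedling H3K9me2, O. brachyantha tillering H3K9me2 and O. brachyantha tillering H3K4me3, which held 2. Lists ranged from 6493 lines (S. bicolor H3K9me2) to 63555 (O. sativa H3K56Ac), and read depth is not in the files. With 15 groups of 1 library, p-values cover chromosomes, peaks, windows or genes within libraries and not plants, and the labels do not say whether the 2 libraries of a group came from separate plants. Scores of peaks are the authors' own.

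At the authors' thresholds H3K9me2 covered the largest share of the chromosomes in O. sativa and the smallest in S. bicolor, but the place of O. sativa depended on weak peaks. Peaks took up 21.0% of the O. sativa chromosomes at tillering and 17.7% ± 1.44 (SD, n = 2) in seedlings. O. glaberrima had 12.4%, O. brachyantha 10.8% ± 2.34 (SD, n = 2) at tillering and 13.5% in seedlings, and L. perrieri 7.08%. O. punctata, which has a larger assembly than O. sativa (393 against 372 Mb), had 2.43%, and S. bicolor had 0.355%. H3K9me2 domains were longest in O. brachyantha, where intervals of at least 10 kb held 65.0% and 65.7% of the bp in the tillering libraries, against 55.1% in O. sativa, 35.7% in O. glaberrima, 23.3% in L. perrieri and 0.999% in O. punctata. With 1 library in most groups, coverage was not tested between species or stages. The tillering libraries of O. brachyantha (9.18% and 12.5%) differed by more than its seedling library did from the higher of them. With a common −log10 q of at least 1, coverage was 0.430% in O. punctata, 3.88% in L. perrieri and 0.0694% in S. bicolor, so these values changed with the threshold. That limit was reached by 16.8% of peaks in S. bicolor, 18.5% in O. punctata and 46.4% in L. perrieri. In O. sativa at tillering it was 75.8% and in O. glaberrima 79.7%. Low coverage may thus come from weak peak calls or from less H3K9me2, which were not told apart. Read depth and the handling of multi-mapped reads, which are not known for these lists, may also have a part. The −log10 q depends on read depth, so the orders at higher limits may reflect depth as well. With a −log10 q of at least 3 in every list the order of O. sativa and O. brachyantha turned, with 0.355% and 8.42% at tillering and 3.22% and 11.5% in seedlings. With at least 2, O. sativa had 2.07% and O. brachyantha 10.2% at tillering, and 14.3% and 12.8% in seedlings. O. glaberrima fell below O. brachyantha as well, to 3.30% with at least 2 and 0.981% with at least 3, and L. perrieri had 0.361% and 0.153%.

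**Figure D1:**
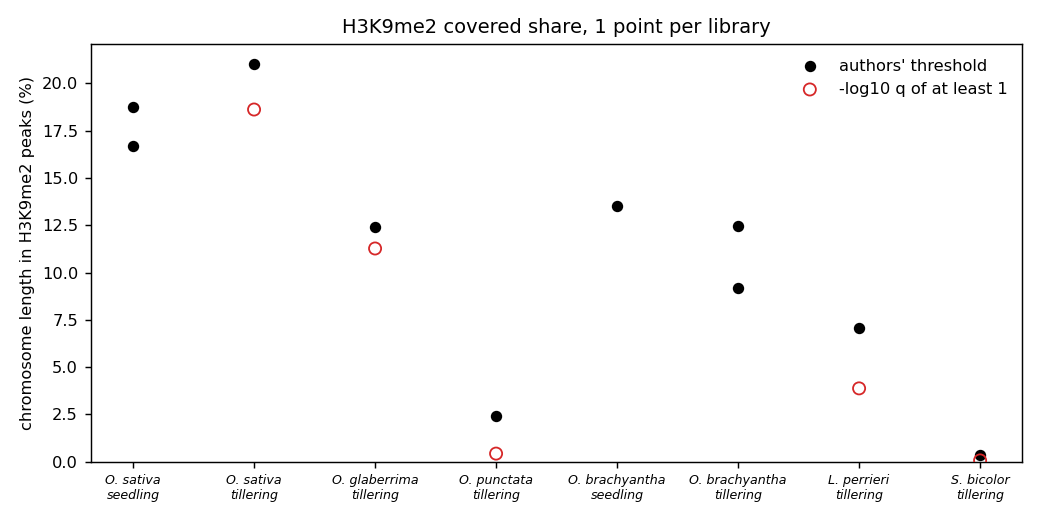
H3K9me2 covered share of the chromosomes in percent (y axis) for each species and stage (x axis), with 1 filled point per library at the authors' threshold and open points for peaks with a −log10 q of at least 1 in the 5 lists that reach lower values. At the authors' threshold the O. sativa libraries lie between 16.7% and 21.0%, above those of O. brachyantha, between 9.18% and 13.5%.

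The positions of H3K9me2 were shared between libraries of a group and between stages. The O. sativa seedling libraries had a Jaccard index of 65.0%, the O. brachyantha tillering batches 69.6% for H3K9me2 and 76.0% for H3K4me3. These were 4.30, 6.92 and 10.2 times the overlap of shifted lists, each with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Of the H3K9me2 bp of O. brachyantha batch 1, 96.8% lay within batch 2 peaks, whereas 71.2% of the batch 2 bp lay within batch 1 peaks. Between seedlings and tillering plants the H3K9me2 Jaccard index was 68.6% ± 3.95 in O. sativa and 73.2% ± 11.3 in O. brachyantha (SD over 2 library pairs). The means were not below the values for libraries of 1 stage, but of the O. brachyantha pairs (65.2% and 81.2%) 1 was. With the 50% of peaks of highest −log10 q the O. sativa stage value was 40.8%, below the 57.3% between its seedling libraries. For H3K4me3 in O. brachyantha the stage values were 64.2% and 65.7%, both below the batch value of 76.0%, a difference that could not be tested with 1 seedling library. By 50% reciprocal overlap, 33.5% of O. sativa and 27.7% of O. brachyantha H3K9me2 peaks were shared between replicates, against 81.3% and 70.6% by any overlap.

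The longest H3K9me2 domains of O. brachyantha held few annotated genes. They were, on assembly RS2, chromosome 1 from 12396463 to 12709923 (313 kb), chromosome 8 from 8030028 to 8337218 (307 kb) and chromosome 10 from 5835054 to 6127946 (293 kb). The other O. brachyantha H3K9me2 libraries covered 97.3% to 99.2% of each, H3K4me3 peaks covered 0%, and the domains overlapped 3, 1 and 0 annotated genes. In O. sativa (tigr6) the longest were chromosome 10 from 3181126 to 3338096 (157 kb), chromosome 6 from 18271145 to 18413632 (142 kb) and chromosome 5 from 9969461 to 10110291 (141 kb), of which the seedling libraries covered 90.6% to 93.0% and H3K4me3 peaks 0%. The longest domains of the other species were 84.9 kb on O. glaberrima chromosome 8 (9210914 to 9295783), 54.0 kb on L. perrieri chromosome 12 (4990019 to 5044050), 21.0 kb on O. punctata chromosome 12 (21367435 to 21388455) and 18.4 kb on S. bicolor chromosome 9 (7688651 to 7707096). Next in length were chromosome 8 from 9845966 to 9917525 and chromosome 3 from 12368986 to 12437395 in O. glaberrima, and chromosome 9 from 3515625 to 3563316 and chromosome 2 from 16959277 to 17006018 in L. perrieri. In O. punctata they were chromosome 1 from 13887151 to 13904501 and chromosome 12 from 21472003 to 21489227, and in S. bicolor chromosome 2 from 91344 to 102187 and chromosome 9 from 7729962 to 7739123.

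Chromosomes differed in their H3K9me2 load, and the order was partly shared between species. Chromosome 12 carried the most in O. brachyantha at tillering (19.1%), O. sativa at tillering (24.9%) and O. punctata (3.49%), and chromosome 10 in O. glaberrima (18.1%) and L. perrieri (10.4%). The lowest were chromosome 1 in O. brachyantha (5.90%) and O. glaberrima (8.72%), chromosome 3 in O. sativa (15.0%) and O. punctata (1.74%), and chromosome 2 in L. perrieri (5%). In seedlings the extremes were chromosomes 12 (23.1%) and 1 (7.42%) in O. brachyantha and chromosomes 4 (21.5%) and 3 (12.6%) in O. sativa. In S. bicolor they were chromosome 9 (0.529%) and chromosome 1 (0.162%). Over the 12 chromosomes, covered shares were positively correlated in all 10 species pairs of Oryza and Leersia, and 7 passed by Spearman's rho and 9 by Pearson's r after adjustment (permutation tests). The highest rho was between O. glaberrima and L. perrieri (rho = 0.909, p = 0.00014, adjusted p = 0.0014; r = 0.881, p = 0.00012, adjusted p = 0.0008). It was followed by O. brachyantha with L. perrieri (rho = 0.853, p = 0.00078, adjusted p = 0.00283; r = 0.868, p = 0.0003, adjusted p = 0.001) and O. punctata with O. brachyantha (rho = 0.846, p = 0.00085, adjusted p = 0.00283; r = 0.875, p = 0.00016, adjusted p = 0.0008). O. sativa with O. punctata was lowest (rho = 0.510, p = 0.0928, adjusted p = 0.0928; r = 0.635, p = 0.0284, adjusted p = 0.0355). Without the 2 chromosomes farthest from the median, r ranged from 0.458 to 0.837, and rho stayed past the threshold for O. glaberrima with L. perrieri (0.855, r = 0.837) and for none of the other 6. Fewer chromosomes were then tested. Chromosome length, which ranged from 15.5 to 33.6 Mb in O. brachyantha, was not accounted for. Its part in the shared order was not tested.

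With 1 block fitted per chromosome, the ratio of H3K9me2 coverage inside to outside, pooled over chromosomes, was highest in O. brachyantha. There the tillering blocks took up 13.8% of chromosome length (35.7 Mb) and held 63.8% of the H3K9me2 bp, with 50.1% coverage inside and 4.54% in the arms, an 11-fold ratio. Seedling blocks took up 14.9% with 56.8% coverage inside and 5.93% in the arms. In O. sativa at tillering the blocks took up 25.4% of the length and held 50.1% of the bp, with 41.4% coverage inside and 14.1% in the arms, a 2.94-fold ratio. The seedling ratio was 3.10. Blocks took up 12.6% of the length in O. glaberrima (4.36-fold), 22.9% in L. perrieri (3.50-fold) and 19.0% in O. punctata (2.95-fold). S. bicolor had a pooled ratio of 2.27. Its mean log2 ratio over chromosomes, 4.06, was above those of the O. brachyantha tillering libraries (3.77 and 3.37). In O. brachyantha at tillering, the block was shortest on chromosome 1, from 12000001 to 12800000 (2.38% of its length), and longest in share on chromosome 9, from the first base to 4400000 (28.4%). On chromosome 12 it ran from 5500001 to 10200000 (27.8%). H3K9me2 was not confined to the blocks, since the arms held the remaining bp. Single O. brachyantha tillering libraries gave 12% and 14.4% of the length, and single O. sativa seedling libraries 21.4% and 25%. The S. bicolor blocks (27.7% of the length) fell to 0.354%, and those of O. punctata to 5.75%, with a −log10 q of at least 1, so neither was well determined. Those of L. perrieri fell to 0.488% and those of O. sativa at tillering to 1.37% with at least 2, and those of O. glaberrima to 0.808% with at least 3. With at least 3, blocks took up 0.591% of the length in O. sativa at tillering and 6.61% in its seedlings, against 10.2% and 14.1% in O. brachyantha.

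**Figure D2:**
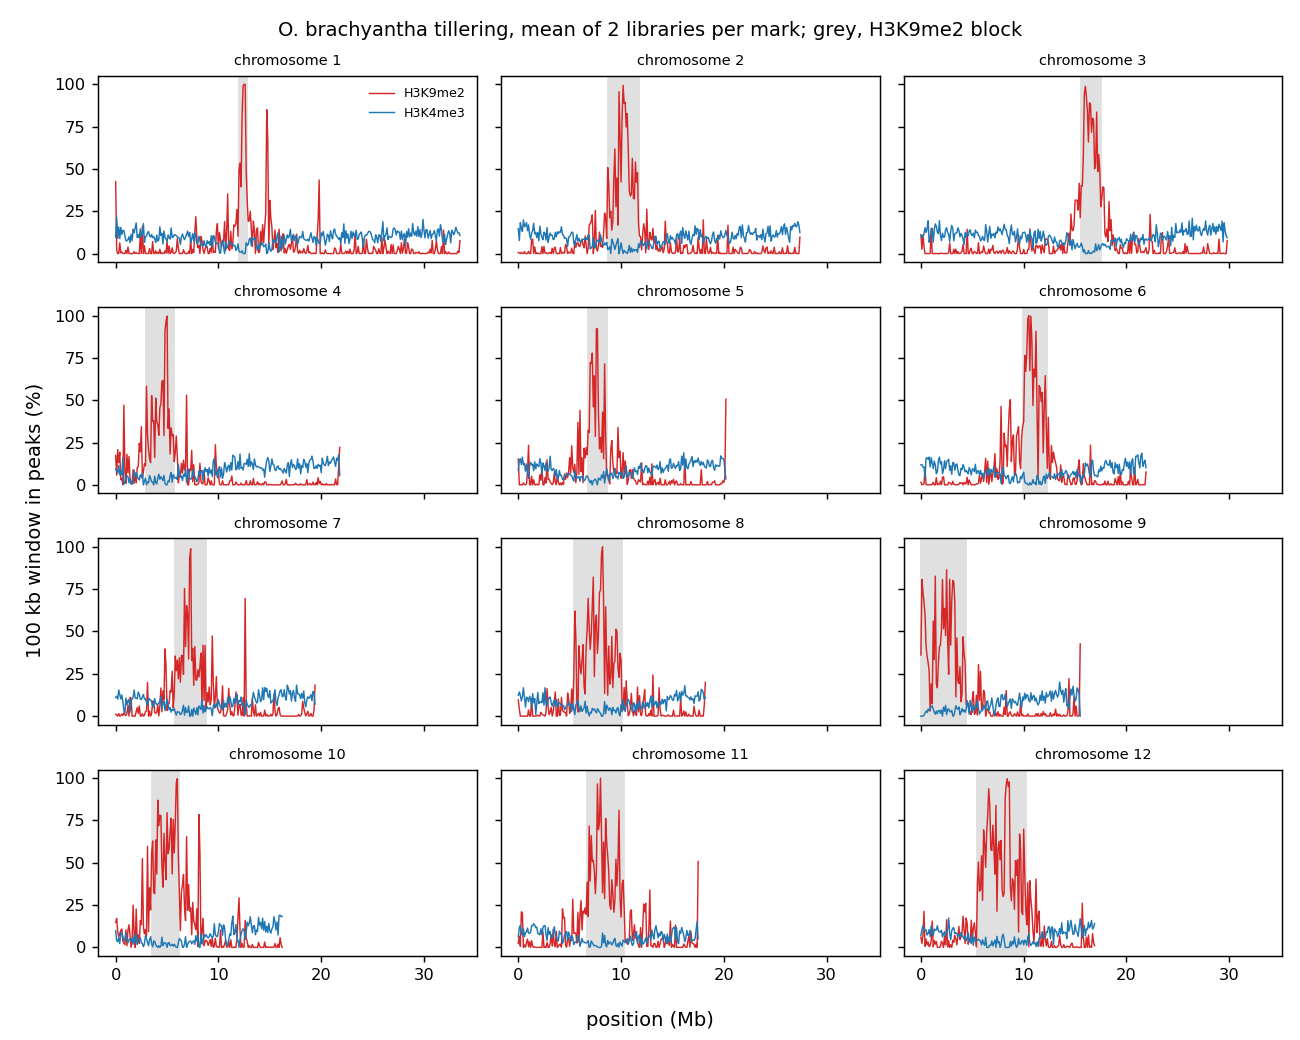
Share of each 100 kb window in peaks (y axis, percent) along the 12 O. brachyantha chromosomes (x axis, Mb) at tillering, for H3K9me2 (red) and H3K4me3 (blue), means of 2 libraries, with the fitted H3K9me2 block in grey. H3K9me2 rises inside each block, which spans 2.38% of chromosome 1 and 28.4% of chromosome 9, and H3K4me3 is low there.

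The other marks differed between the H3K9me2 block and the arms on nearly all chromosomes. H3K27me was higher in the block, by 2.88 ± 0.42 on the log2 scale in O. brachyantha and 1.45 ± 0.28 in O. sativa (mean ± SD over 12 chromosomes), on 12 of 12 chromosomes in both. The marks of active genes were lower in the block on 12 of 12 chromosomes. Coverage alone cannot tell this from sparse genes, since the O. brachyantha blocks held 28.3 protein-coding genes per Mb and the arms 99.6. In O. brachyantha at tillering the log2 ratio was −2.02 ± 0.47 for H3K4me2, −1.92 ± 0.47 for H3K9Ac, −1.86 ± 0.42 for H3K4me3 (−1.86 in each batch) and −1.80 ± 0.42 for H3K56Ac. H3K4me3 in O. brachyantha seedlings had −1.79 ± 0.39, H3K56Ac in O. sativa seedlings −1.30 ± 0.38 and H3K4me3 in O. sativa at tillering −1.19 ± 0.45. The O. sativa H3K56Ac list keeps uniquely mapped reads, unlike the H3K9me2 lists that set the block, and the part of this was not tested. H3K27me2 changed least, with −0.76 ± 0.57 and 11 of 12 chromosomes lower in the block. Each of the 10 comparisons passed the two-sided exact sign-flip test, with p = 0.000977 (adjusted 0.000977) for H3K27me2 and p = 0.000488 (adjusted 0.000543), the smallest the test can give, for the 9 others.

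**Figure D3:**
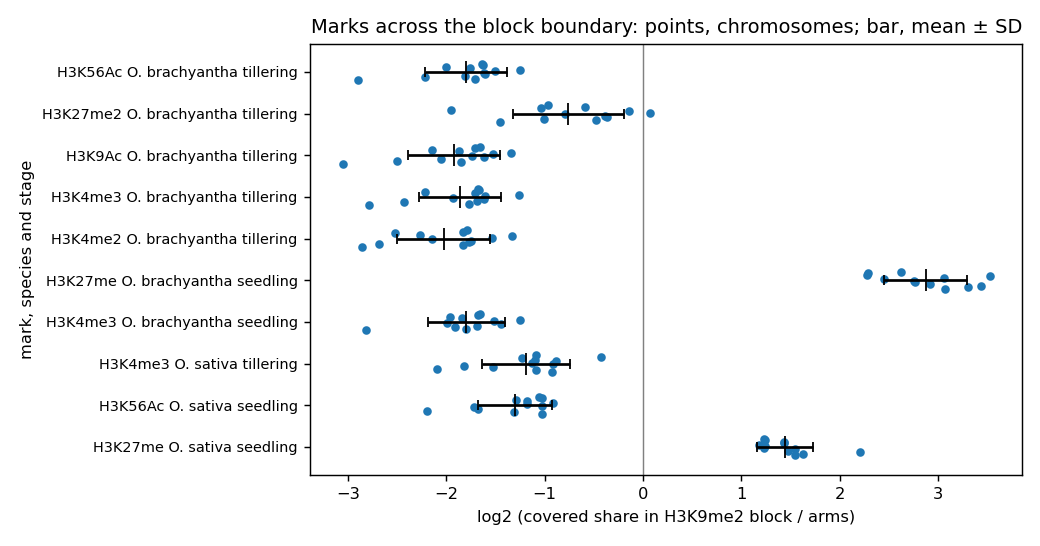
Log2 ratio of the covered share in the H3K9me2 block to that in the arms (x axis) for each mark, species and stage (y axis). Points are the 12 chromosomes, and bars give the mean and SD over chromosomes. The H3K27me points lie to the right of 0 and those of the 4 marks of active genes to the left, while H3K27me2 (mean −0.76) has 1 point above 0.

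H3K9me2 shared sequence with H3K27me and almost none with the marks of active genes. Shared bp of H3K9me2 and H3K27me were 4.94 times the value for shifted lists in O. brachyantha seedlings and 3.21 times in O. sativa seedlings. With shifts within block and arms the ratios were 2.13 and 2.51, so the order of the species turned. The O. brachyantha seedling lists share an input, whereas each O. sativa seedling list has its own control. The part of this in the ratios was not tested. For H3K9me2 and H3K4me3 the ratio was 0.00648 in O. brachyantha at tillering, 0.0236 in its seedlings and 0.0229 in O. sativa. H3K9me2 with H3K9Ac, H3K56Ac and H3K4me2 gave 0.00617, 0.00997 and 0.0369 in O. brachyantha (0.00409 to 0.00825 for H3K9Ac, 0.00619 to 0.0138 for H3K56Ac with single H3K9me2 libraries), and H3K9me2 with H3K56Ac gave 0.00862 in O. sativa (0.00286 and 0.0144 with single H3K9me2 libraries). H3K27me had little in common with H3K4me3 in O. brachyantha (0.0372) and with H3K56Ac in O. sativa (0.0463). The O. sativa H3K56Ac list keeps uniquely mapped reads, whereas the O. sativa seedling H3K9me2 and H3K27me lists place multi-mapped reads at 1 random site. The part of this difference in the O. sativa ratios was not tested, and the handling in O. brachyantha is not known. The marks of active genes coincided, from 4.71 times for H3K4me2 with H3K9Ac to 10.3 times for H3K9Ac with H3K56Ac. H3K27me2 shared sequence chiefly with H3K4me2, at a ratio of 4.92, or 8.29 with the 50% of peaks of highest −log10 q. Its ratios with H3K4me3, H3K56Ac and H3K9Ac were 3.77, 3.40 and 2.65, and with that filter 1.41, 2.50 and 1.78. Of 22 pairs, 21 passed the two-sided permutation test, 12 above and 9 below the shifted value, with an adjusted p of at most 0.00214 from the smallest p the shifts can give (0.002). H3K9me2 with H3K27me2 did not pass (1.07, permutation p = 0.194, adjusted p = 0.194), and its direction depended on the peaks used, with 0.673 for the 50% of peaks of highest −log10 q and 1.32 for shifts within block and arms. Over 100 kb windows, H3K9me2 and H3K4me3 coverage were inversely related in every library pair tested, with rho of −0.645 in O. sativa at tillering, −0.697 in O. brachyantha seedlings, and −0.619 and −0.673 in tillering batches 1 and 2 (permutation p = 0.001 each, the smallest possible; neighbouring windows are not independent).

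**Figure D4:**
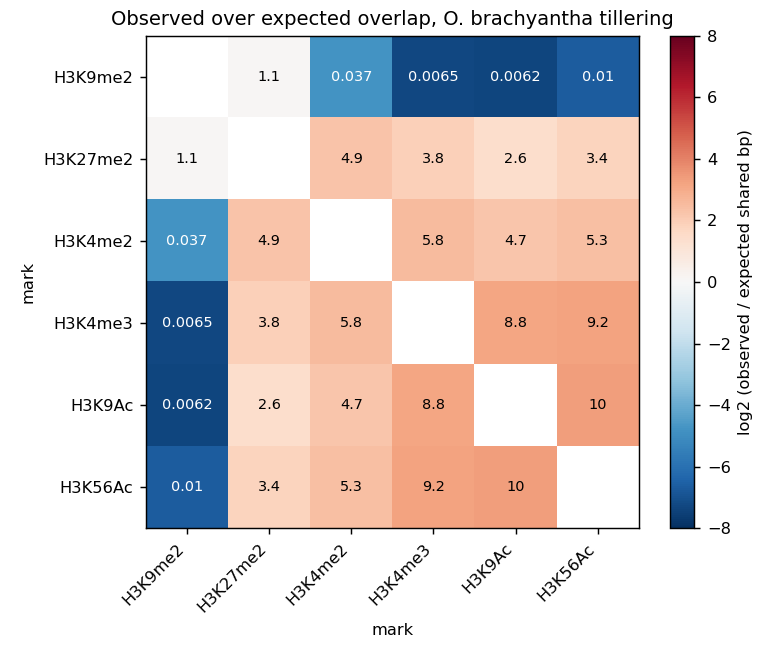
Shared bp of each pair of marks (both axes) in O. brachyantha at tillering over the mean of 1000 shifted lists, given as a ratio in each cell and coloured by its log2. H3K9me2 is far below 1 with H3K4me2, H3K4me3, H3K9Ac and H3K56Ac, and near 1 (1.07) with H3K27me2.

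Among O. brachyantha genes, H3K9me2 lay on rRNA genes far more often than on others. At least 50% of the body was covered in 69 of 70 rRNA genes in seedlings (98.6%, against 1.75% of other genes) and in 92.1% at tillering (60 and 69 genes in the 2 libraries), and H3K27me covered the same number, 69. Most of them lie at 1 locus, with 59 of the 70 on chromosome 11 between 7705924 and 7851291, all marked in each H3K9me2 list. The other 11 lie on chromosome 9, and 1 of these was marked in each H3K9me2 list. The genes unmarked in batch 1 alone are among these 11. All 70 lie inside fitted H3K9me2 blocks, whereas 22221 protein-coding genes lie in the arms and 1009 in the blocks. None of the 70 had a peak of H3K4me3, H3K4me2, H3K9Ac or H3K56Ac. Pseudogenes carried H3K9me2 more often than other genes in seedlings (6.34% against 1.81%, a difference of 4.52 points where shifted peaks gave 1.18, two-sided permutation p = 0.016, adjusted p = 0.0211) and had 3.44% against 1.27% at tillering (2.17 points, permutation p = 0.272, adjusted p = 0.333, with 3.49 and 0.853 points without batch 1 and without batch 2). The difference between the stages was not tested, and the seedling call was lost with the 50% of peaks of highest −log10 q (adjusted permutation p = 0.133). H3K27me lay on 11.2% of pseudogenes and 8.18% of lncRNA genes, against 2.24% and 2.38% of other genes (permutation p = 0.002 and 0.004, adjusted p = 0.00277 and 0.00539). The 4 marks of active genes were rarer in each of the 6 classes than in other genes, with snoRNA genes and H3K4me2 the exception that did not pass (permutation p = 0.0559, adjusted p = 0.0719). H3K4me3 at tillering, for example, was at an end of 48.5% of pseudogenes, 48.2% of lncRNA, 49.7% of snoRNA, 20.0% of snRNA and 15.6% of tRNA genes, against 76.8% to 78.0% of the others. The snoRNA call for H3K4me3 was lost with the 50% of peaks of highest −log10 q in both stages, and for pseudogenes the H3K4me2 difference then changed sign (0.107 points). H3K27me2 was more common on pseudogenes (18.8% against 14.5%) and rarer on the 5 other classes. In total 41 of 54 comparisons passed, 7 above and 34 below the shifted value, with rRNA and H3K9me2 at the smallest p the shifts can give (0.002, adjusted 0.00277).

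Protein-coding genes were sparse in the O. brachyantha blocks, with 28.3 per Mb against 99.6 per Mb in the arms. A larger share of block genes carried H3K9me2, which follows in part from fitting the block to H3K9me2. In seedlings H3K9me2 covered at least 50% of the body of 10.4% of block genes (105) and 0.959% of arm genes (213). The tillering batches had 5.85% and 9.32% in the block and 0.428% and 0.801% in the arms. Even so, 72.9% and 74.4% of block genes had H3K4me3 at an end in the batches, against 81.1% and 82.1% of arm genes. The difference in this share was small beside that in gene density. These shares describe the libraries and were not tested.

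H3K9me2 covered at least 90% of the body of 72 protein-coding genes in each of the 3 O. brachyantha libraries, and 33 of them lay in a block. None of the 72 had H3K4me3 at an end in all 3 H3K4me3 libraries. The longest was LOC121055200 on chromosome 8 (8170404 to 8343497, 173094 bp, RS2), covered at 96.0% to 96.5% and overlapping the second longest H3K9me2 domain, with 32.7% under H3K27me. LOC107304349 on chromosome 6 (10926962 to 10943240) followed with 16279 bp and 96.1% to 100%. Both lie in blocks, as do LOC121055202 (chromosome 8, 8881668 to 8885172), LOC121055319 (chromosome 9, 2613281 to 2616523), LOC102703896 (chromosome 9, 2745081 to 2748278) and LOC121053502 (chromosome 2, 11459135 to 11462192). In the arms were LOC121054431 (chromosome 5, 9711945 to 9721037), LOC121054417 (chromosome 5, 5021040 to 5029037), LOC121055678 (chromosome 11, 12206838 to 12210318) and LOC102700382 (chromosome 11, 12344167 to 12347309). H3K27me covered 80.9% to 100% of these 9 shorter genes, and none of the 10 had H3K4me3 at an end in any library. Their products are not given in the sources used here. Without tillering batch 1 the count was 116 genes.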

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

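The contrasts between species and stages, the comparison of arm coverage, and the tests of weak peaks, of interval joining and of peaks of other marks on the rRNA genes were chosen only after the result was seen.

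H3K9me2 and H3K27me stood out more from the arms in O. brachyantha than in O. sativa. On the log2 scale the block over arms ratio was higher in O. brachyantha by 1.47 (seedling H3K9me2), 1.89 (tillering H3K9me2) and 1.43 (seedling H3K27me), each on 12 of 12 chromosomes paired by number (exact sign-flip test, adjusted p = 0.000684). With a −log10 q of at least 2 the differences were 1.38, 2.45 and 1.48, and with at least 3 they were 1.13, 3.55 and 2.26, again on 12 of 12 chromosomes. Blocks were fitted in each species and stage by itself and kept from the fit to all peaks. They took up 25.4% of the length in O. sativa and 13.8% in O. brachyantha at tillering, and 23.1% and 14.9% in seedlings. The contrasts thus compare regions of unlike extent, and the part of this was not tested. With 1 or 2 libraries per group, the p-values cover chromosomes and not plants. In O. sativa at tillering at least 3 left few peaks, with 0.463% of the block and 0.318% of the arms covered. Its mean log2 ratio was then 0.519, against 4.07 in O. brachyantha, so the larger tillering difference rests on a nearly empty list. For H3K4me3 at tillering O. brachyantha was lower by a difference of −0.68, on 11 of 12 chromosomes (adjusted p = 0.00171, exact sign-flip test). Between stages, H3K9me2 was higher at tillering by 0.29 in O. brachyantha and differed by −0.13 in O. sativa (adjusted p = 0.000684 each, exact sign-flip test). Both differences are smaller than the gap between libraries of 1 group, with 3.77 and 3.37 in the O. brachyantha tillering batches and 1.88 and 1.72 in O. sativa seedlings, although the single library of the other stage (3.28 and 1.67) lay below both. For H3K9me2 itself the positive sign follows from how the block was fitted. H3K4me3 in O. brachyantha did not differ detectably between stages (−0.07, adjusted p = 0.229, exact sign-flip test).

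At the authors' thresholds the arms of O. sativa were more covered by H3K9me2 than those of O. brachyantha, at 12.7% ± 1.60 against 5.01% ± 1.33 (SD, 3 libraries each over 2 stages; exact permutation p = 0.1, the smallest 3 against 3 can give). Weak peaks in the O. sativa lists may account for this, since with a −log10 q of at least 2 in all 6 lists the ratio was 1.47 (both O. sativa seedling libraries, at 8.24% and 9.96%, still above each O. brachyantha library, and the tillering library, at 1.57%, below), and with at least 3 it was 0.356, with the lowest O. sativa library at 0.318% and the highest of O. brachyantha at 4.26%. Longer joined intervals are argued against, since O. sativa had 2.85 times as many peaks per Mb of arm at the authors' thresholds. The handling of multi-mapped reads, which the lists of O. brachyantha do not state, and the read depth, on which −log10 q depends and which is not in the files, stay open, as does a difference between the species, which was not tested apart from these. The 50% of peaks of highest −log10 q per list left each O. sativa library (lowest 7.67%) above each of O. brachyantha (highest 4.65%). This filter thins both species alike and decides nothing.

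In O. brachyantha at tillering, batch 1 H3K9me2 covered 9.18% of the chromosomes and batch 2 12.5%. Batch 2 peaks that batch 1 missed had a median −log10 q of 0.472 times that of the peaks it shared (1.77 against 3.76). Lower sensitivity of the batch 1 library predicted a ratio below 1. Less H3K9me2 in batch 1 would give this as well, so the ratio does not separate them. The median pileup at a peak was 7.03 in batch 1 and 15.65 in batch 2, and the median fold enrichment 3.16 and 2.38. Complete loss of wide regions is argued against, as 4 of 830 batch 2 domains of at least 10 kb (0.482%) had no batch 1 peak. Partial loss could not show, since any batch 1 peak in a domain counted. The design gives no biological difference between the batches to test.

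The O. brachyantha rRNA genes lay under H3K9me2 without marks of active genes. A read pileup on collapsed repeats in every antibody is argued against, since 0% of the 70 genes had a peak of H3K4me3, H3K4me2, H3K9Ac or H3K56Ac, although the treatment of multi-mapped reads in these lists is unknown and their exclusion could also leave such lists empty there. Position inside a wide H3K9me2 region fitted, since 83.3% of the other genes within 20 kb were marked as well, but there are 6 such genes. All 70 rRNA genes also lie in the fitted blocks of chromosomes 9 (1 to 4400000) and 11 (6700001 to 10300000). Of protein-coding block genes over all chromosomes, 10.4% were marked in seedlings. Whether the marked rRNA copies are silent was not measured, and 59 of them form 1 cluster.

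Unplaced contigs, which the comparisons leave out, held a sizeable share of the bp in some lists. It was 9.12% in O. brachyantha seedling H3K9me2, 12% and 9.92% in tillering batches 1 and 2, 5.39% in seedling H3K27me and 14.8% in S. bicolor H3K9me2. In the other O. brachyantha lists it was 0.121% for H3K27me2, 0.0518% for seedling H3K4me3, 0.0403% and 0.0415% for tillering H3K4me3, 0.0487% for H3K56Ac, 0.0439% for H3K9Ac and 0.0245% for H3K4me2.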

How the results depend on the processing

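The common −log10 q of at least 1, 2 and 3 and the fit with each arm at its own mean were chosen only after the data were seen. Of 522 alternative values for 147 results, 409 kept direction and call or stayed within the limits below, 14 lost and 15 gained a call, 80 moved and 4 reversed. A value without a test counted as moved beyond 1 SD between libraries, or with 1 library beyond a 95% binomial interval, which is very narrow for covered bp, and a count beyond 1.5 times. Unless a sentence says otherwise, the cause was not tested. Read depth is not in the files, so its part was not tested.

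Covered percent moved as follows, by construction, since each setting changes the peaks or the length used. With the 50% of peaks of highest −log10 q it was 13.5 and 11.8 in O. sativa seedlings and tillering plants, 7.19 in O. glaberrima, 1.27 in O. punctata, 12 in O. brachyantha seedlings, 4.27 in L. perrieri and 0.181 in S. bicolor. With −log10 q of at least 1 it was 18.6 in O. sativa, 11.3 in O. glaberrima, 0.430 in O. punctata, 3.88 in L. perrieri and 0.0694 in S. bicolor. With peaks joined it was 19.7 and 22.5 in O. sativa seedlings and tillering plants, 13.7 in O. glaberrima, 2.76 in O. punctata, 14.1 in O. brachyantha seedlings, 8.22 in L. perrieri and 0.364 in S. bicolor. With −log10 q of at least 2 it was 14.3 and 2.07 in O. sativa seedlings and tillering plants, 3.30 in O. glaberrima, 0.125 in O. punctata, 12.8 in O. brachyantha seedlings, 0.361 in L. perrieri and 0.0275 in S. bicolor. With at least 3 it was 3.22 and 0.355 in O. sativa, 0.981 in O. glaberrima, 0.0935 in O. punctata, 11.5 and 8.42 in O. brachyantha seedlings and tillering plants, 0.153 in L. perrieri and 0.0141 in S. bicolor, so O. brachyantha then stood above O. sativa. Lengths from the H3K9me2 list gave 21.1 in O. sativa at tillering and 13.5 in O. brachyantha seedlings, and unplaced contigs gave 14.6 in the latter and 0.388 in S. bicolor.

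Block length percent with the 50% of peaks was 16.5 and 17.9 in O. sativa seedlings and tillering plants, 10.3 in O. glaberrima, 15.9 in L. perrieri and 25.5 in S. bicolor. With −log10 q of at least 1 it was 23.9 in O. sativa, 5.75 in O. punctata, 18.9 in L. perrieri and 0.354 in S. bicolor. With at least 2 it was 18.5 and 1.37 in O. sativa seedlings and tillering plants, 9.45 in O. glaberrima, 0.941 in O. punctata, 0.488 in L. perrieri and 0.184 in S. bicolor. With at least 3 it was 6.61 and 0.591 in O. sativa, 0.808 in O. glaberrima, 0.789 in O. punctata, 10.2 in O. brachyantha at tillering, 0.488 in L. perrieri and 0.169 in S. bicolor. With each arm at its own mean it was 18.6 and 21.1 in O. sativa, 13.8 in O. punctata and 19.4 in L. perrieri. Windows of 500 kb gave 15.6 in O. glaberrima, 20.2 in O. punctata, 26.1 in L. perrieri and 38.1 in S. bicolor, and windows of 50 kb 17.4 in O. punctata and 30.9 in S. bicolor. Leaving out a batch gave 12 to 14.4 in O. brachyantha at tillering, and 72 to 116 genes under 90% H3K9me2.

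The stage Jaccard index with the 50% of peaks was 40.8 for O. sativa H3K9me2 (57.3 between its seedling libraries) and 59.0 for O. brachyantha H3K4me3. By 50% reciprocal overlap, replicates shared 33.5% and 27.7% of H3K9me2 peaks in O. sativa and O. brachyantha and 77.6% of H3K4me3 peaks, and stages 35.3%, 34.6% and 63.6%. Replicate overlap with a library left out gives no value, and alternatives for the product-based gene lists were not run, as no gene could be matched.

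H3K9me2 with H3K27me2 reversed to 0.673 with the 50% of peaks, and passed at 1.22 by peak counts and at 1.32 with shifts within block and arms. Pairing by batch (the replicate block) gave 0.00678 for H3K9me2 with H3K4me3 and changed no call. Correlations that lost the call without the 2 farthest chromosomes, with fewer chromosomes as part of the cause, had rho of 0.648 (O. sativa and O. glaberrima), 0.394 (O. sativa and O. brachyantha), 0.600 (O. sativa and L. perrieri), 0.612 (O. glaberrima and O. brachyantha), 0.745 (O. punctata and O. brachyantha) and 0.758 (O. brachyantha and L. perrieri). With the 50% of peaks the O. sativa pairs with O. brachyantha and L. perrieri had 0.469 and 0.615, and O. glaberrima with O. brachyantha 0.594. With −log10 q of at least 1 the O. sativa pairs had 0.448 and 0.552.

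For gene classes (class minus other genes, in points), the 50% of peaks ended the calls of pseudogenes for seedling H3K9me2 (3.15) and of snoRNA genes for H3K4me3 (−12.5 and −7.47), made that of snoRNA genes for H3K4me2 (−39.2) and reversed pseudogenes for H3K4me2 (0.107). With 10% of the body, seedling lncRNA genes (6.48) and tillering pseudogenes (5.23) for H3K9me2 and snoRNA genes for H3K27me (2.33) passed, and tRNA genes for seedling H3K9me2 reversed (−1.33). The tRNA difference at tillering was −0.558 to 0.367 with a batch left out. Any overlap with the body made the snoRNA call for H3K4me2 (−49.2). Fisher's exact test, which treats neighbouring genes as independent, made those of seedling lncRNA (1.77) and snoRNA (4.14) for H3K9me2, tRNA (−1.59) and snoRNA (5.58) for H3K27me, tillering pseudogenes for H3K9me2 (2.17) and snoRNA for H3K4me2 (−22.9). Among genes under H3K27me2, the H3K4me3 difference passed with the 50% of peaks (−44.9 and −46.6).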

Other observations

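The comparisons in this part were chosen only after the data were seen.

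Genes under H3K27me2 and genes under H3K9me2 were each compared with the remaining genes in O. brachyantha tillering plants, and not with each other. Of 3588 protein-coding genes with H3K27me2 on at least 50% of the body, 99.5% had H3K4me2 at an end, against 82.5% of other genes (17.0 points, where shifted peaks gave 2.28). H3K9Ac was at 47.4% against 77.9% (−30.6 points, shifted −9.89) and H3K56Ac at 61.1% against 82.3% (−21.2 points, shifted −8.26), each with an adjusted p of 0.00231 from the smallest two-sided permutation p, 0.002, over 15 comparisons. H3K4me3 was at 75% and 79.8% in batches 1 and 2, against 81.8% and 82.2%, and did not pass (permutation p = 0.855 and 0.0639, adjusted p = 0.855 and 0.0685). With the 50% of peaks of highest −log10 q the H3K4me3 difference passed as well, at −44.9 and −46.6 points. Genes under H3K9me2 had each of the 4 marks of active genes at 19.5% to 23.2%, against 73.6% to 85.9% of other genes (adjusted permutation p = 0.00231 for each of the 10 comparisons).

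The stretch of low H3K4me3 was wider than the H3K9me2 block. With the same fit applied to H3K4me3, its trough reached beyond the H3K9me2 block at 23 of 23 edges in O. brachyantha at either stage and at 22 of 23 in O. sativa. The median distance was 3.0 Mb (quartiles 2.2 and 3.55) in O. brachyantha at tillering, 2.7 Mb in its seedlings and 4.2 Mb in O. sativa. In O. brachyantha at tillering H3K9me2 coverage was 4.45% at 2.5 to 3 Mb outside the block. It was 16.5% in the last 0.5 Mb outside and 44.6% in the first 0.5 Mb inside. This last step follows in part from fitting the block to H3K9me2. H3K4me3 coverage at the same places was 7.61%, 4.66% and 3.01%. The edges depend on a fit with 1 block per chromosome, and graded edges were not simulated. Protein-coding genes were sparser in the O. brachyantha blocks than in the arms (28.3 against 99.6 per Mb). The part of gene density in the width of the trough was not tested.

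The protein-coding genes with H3K4me3 or H3K9me2 varied between libraries of O. brachyantha, and whether stages differ more than batches was not tested. For H3K4me3, seedlings differed from batches 1 and 2 in 2437 and 2130 genes, and the batches from each other in 1693. H3K4me3 was at an end of 17652 genes in all 3 libraries, of 1051 in seedlings and in neither batch, and of 386 in both batches and not in seedlings. For H3K9me2 on the body the numbers were 149, 61 and 3, with 122 differing between batches, of which 120 were marked in batch 2, and 174 and 76 between seedlings and batches 1 and 2. At the 50% body limit, 30 genes carried both H3K9me2 and H3K4me3 in every library.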
